A study of Homo sapiens with 12 samples.

How the data were processed

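HLE B-3 is an immortalised line of human lens epithelial cells. The study measured RNA from these cells after 4 h or 16 h with 1 µM dexamethasone, a synthetic glucocorticoid, or with vehicle, on Affymetrix HUM_133A arrays. There were 12 arrays in 4 groups of 3: vehicle 4 h, dexamethasone 4 h, vehicle 16 h and dexamethasone 16 h. The labels give a replicate number for each array but do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

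The deposited values are intensity signals, 1 per probe set and array, which the authors extracted with Affymetrix Microarray Suite (MAS5). They are linear, at least 0, and not on a common scale: the 2% trimmed mean ran from 105.4 to 335.9 between arrays. The labels state no scaling target, no detection calls and no filter. The table holds 22283 probe sets, of which 68 control probe sets were left out of the tests, leaving 22215. For arrays the number of samples limits the precision.

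Each array was rescaled to the same 2% trimmed mean (203.2, the mean of the 12 trimmed means), and log2 values were taken after adding a pseudocount of 5% of it (10.16). Probe sets were kept when their mean rescaled signal over the 12 arrays was at least 20% of the trimmed mean (40.65), which kept 12546 probe sets (56.5%). Gene names came from the array's annotation table: 19065 of the 22215 probe sets name 1 gene, 1043 name several and 2107 name none. Among the kept probe sets these numbers are 11157, 597 and 792. Symbols were brought up to date through the Entrez ID, which changed 0 symbols, and 12 named probe sets had no match in the gene table. Positions are on GRCh38.p14. A probe set that the annotation leaves unnamed stays unnamed here.

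Differences were tested with limma 3.58.1 in R 4.3.3: 1 mean per group, moderated variances with a trend on the mean level, two-sided, Benjamini-Hochberg adjusted over the 12546 probe sets, with a threshold of 0.05. The comparisons were dexamethasone minus vehicle at 4 h and at 16 h, the difference between these effects (16 h minus 4 h, an interaction), and vehicle 16 h minus vehicle 4 h. Fold changes are given as log2 values with the standard error of the fit, and signals as rescaled means with the SD.

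These choices, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined, with 1 change made afterwards. Vehicle 16 h replicates 1 and 3 differed far less from each other than any other replicate pair did, so they were averaged and counted as 1 sample. This gave 11 samples, 2 of them vehicle 16 h, and 7 residual degrees of freedom. The fixed design had counted 12 separate arrays with 8 residual degrees of freedom. The change was made after the data, and also the counts of the averaged fit, had been seen. With 12 separate arrays the counts past the threshold were 1270 in place of 767 at 4 h, 156 in place of 35 at 16 h, 707 in place of 40 for the interaction and 3256 in place of 1886 for time.

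The rule for named genes took, for each dexamethasone comparison, the 15 largest rises and the 15 largest falls. They were chosen among probe sets that passed the threshold, named a single gene and had all dexamethasone arrays beyond all vehicle arrays. For the interaction and for time it took the 6 largest in each direction. It also took up to 4 members of each gene list with the smallest p, and FKBP5, TSC22D3, PER1, DUSP1 and NR3C1 as checks of the treatment. A gene named outside this rule was chosen after its values were seen.

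There were 21 gene lists, with 1 probe set per gene (the brightest kept probe set that names only that gene, 7701 genes). They were tested with camera from limma at its preset correlation between genes of 0.01 and again with an estimated correlation, two-sided, adjusted over the 21 lists within each comparison. The overlap of the responses at 4 h and 16 h was tested with a one-sided Fisher's exact test. For comparisons that share controls, unchanged groups were simulated 20 times with the residual spread of each probe set, and means over the simulations are given. Array measures were compared between groups with two-sided exact permutation tests, which cannot go below 0.1 for 3 against 3. Marker genes of 7 cell types were read as levels.

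The steps were tested on simulated data with 12546 probe sets and the same group sizes, in which 100 probe sets changed by a log2 value of 1 and another 100 by 2. At a change of 1, 67 were recovered for dexamethasone at 4 h, 57 at 16 h, 27 for the interaction and 58 for time. At a change of 2 the numbers were 95, 89, 79 and 95. False calls made up 6.9%, 3.31%, 2.75% and 6.71% of the calls, and 0 calls were made with nothing changed. The simulated noise was independent between probe sets and arrays. These shares therefore do not cover shifts that many probe sets of an array have in common.

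The alternatives were quantile normalization, no rescaling and median centring in place of the rescaling, a pseudocount of 1% or 20%, no level filter or one at 40%, no variance trend, only the arrays of a comparison, the replicate number as a block, a mean over a gene's probe sets for the lists, and leaving out each array in turn. Added after seeing the data were cyclic loess, 12 separate arrays (also for the block), array quality weights, and leaving out dexamethasone 16 h replicate 2 and vehicle 4 h replicate 3 together. No fixed criterion chose these arrays: dexamethasone 16 h replicate 1 lay as far from its group as vehicle 4 h replicate 3 (root mean square deviations of 0.295 and 0.291). Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.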

Results

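RNA levels were measured on 12 arrays of HLE B-3 human lens epithelial cells, 3 each for vehicle and 1 µM dexamethasone at 4 h and at 16 h. The lens chaperone crystallin CRYAB had a mean rescaled signal of 6980 and the eye transcription factor PAX6 one of 2480, above 99.2% and 97.5% of the probe sets. With MAF (122) and CRYAA (53.2), 4 of 8 lens markers lay above the level filter, and CRYBB2, BFSP1, MIP and FOXE3 lay below it. Of the fibroblast markers 4 of 7 lay above it, with COL1A1 at 6160 and THY1 at 1300, and COL3A1, PDGFRA and LUM lay below it. Above the filter were also 1 of 6 keratinocyte markers on the array (SFN, 392), 2 of 5 pigment cell markers (TYR, 67.0, and MITF, 79.8), and 1 of 5 each for macrophage (CD14, 74.3), lymphocyte (CD3E, 64.7) and endothelium (PECAM1, 61.9). The filter kept 56.5% of all probe sets, so these counts alone do not tell the cell types apart. No marker above the filter passed the test with dexamethasone at 4 h or at 16 h, and markers below it were not tested.

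The arrays differed in scale and quality along with the groups. At 4 h the deposited 2% trimmed mean was 296 ± 37 with dexamethasone and 236 ± 13 with vehicle (SD, n = 3 each), the ratio of the 3' to the 5' GAPDH probe sets was 0.865 ± 0.011 against 0.893 ± 0.010, and the rescaled median was 57.6 ± 1.4 against 47.5 ± 3.7. Each of these differences reached a two-sided exact permutation p of 0.1, the smallest possible for 3 against 3. The 3' to 5' ratio of ACTB did not (1.1 ± 0.046 with dexamethasone against 1.17 ± 0.096 with vehicle, exact permutation p = 0.5). At 16 h the trimmed mean was 119.5, 206.5 and 105.4 on the dexamethasone arrays and 149.2, 120.6 and 142 on the vehicle arrays (exact permutation p = 1 for 3 against 2 samples). Vehicle 16 h replicates 1 and 3 were nearly identical. For the 1117 brightest probe sets the median absolute deviation of their log2 ratio was 0.0366, against 0.15 to 0.305 for the other 11 replicate pairs, and they were counted as 1 sample. Dexamethasone 16 h replicate 2 stood apart, with a mean correlation of 0.9491 to its own group and a rescaled median of 73.3.

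The first comparison asked how the cells responded to dexamethasone within 4 h. TSC22D3 (gene identifier 1831, chromosome X, 107713221 to 107775988), which encodes a glucocorticoid-induced leucine zipper protein, rose from a rescaled signal of 275 ± 25 with vehicle to 1520 ± 79 with dexamethasone (SD, n = 3 each). That is 5.38-fold after the pseudocount, which lowers folds most at small signals, with a log2 change of 2.43 ± 0.12 (SE) with an adjusted p of 1.5e-07. CCL2 (gene identifier 6347, chromosome 17, 34255285 to 34257203), a chemokine that attracts monocytes, fell from 243 ± 60 to 43.8 ± 9.6, or 4.67-fold, with a log2 change of -2.22 ± 0.20 and an adjusted p of 0.00011. The largest rise by fold was SPDL1, a mitotic spindle protein, from 9.26 ± 8.4 to 128 ± 36 (log2 2.89 ± 0.32). Its vehicle signal lies below the pseudocount of 10.16, which limits the fold. At 16 h the SPDL1 signal was 91.5 ± 3.5 with vehicle and 141 ± 47 with dexamethasone, which did not pass. Signals of 357 ± 140 with vehicle and 1150 ± 140 with dexamethasone were found for the transcription factor SOX4 by the brightest of its 4 kept probe sets (log2 1.73 ± 0.24). The other named risers, with log2 changes from 1.63 to 2.22, were ELL2, HSPA4, KLF4, ZNF532, ORC3, PRKAR1A, EPB41L3, SERINC1, CACNA1I, PICALM, ARHGEF28 and WDFY3. Another probe set of CACNA1I went the other way. Vehicle 4 h signals lay below the filter level of 40.65 for ELL2, HSPA4, KLF4, ZNF532, ORC3, CACNA1I, PICALM, ARHGEF28 and WDFY3 (11.4 to 26.9). The folds of these probe sets depend on the pseudocount. Their signals were 54.5 to 113 with dexamethasone at 4 h and 51.5 to 145 in vehicle at 16 h. The brighter KLF4 probe set rose from 131 ± 22 to 410 ± 38 (log2 1.58 ± 0.15). Signals in vehicle 4 h, dexamethasone 4 h and vehicle 16 h were 103, 333 and 319 for PRKAR1A. They were 62, 212 and 172 for SERINC1, and 48.8, 175 and 97.5 for EPB41L3. The other named falls, from -0.79 to -2.01, were SUGP1, the glucose transporter SLC2A3, MED18, CFAP410, DENND2D, the hedgehog transcription factor GLI1, MRPL4, IER3, ENC1, the Notch target HES1, CDC42EP2, MAPKBP1, F12 and POLD4. With dexamethasone the signals of SUGP1, SLC2A3, MED18, CFAP410, DENND2D and GLI1 (15.2 to 37.6) lay below the filter level, so their folds also depend on the pseudocount.

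Among the glucocorticoid-induced genes fixed in advance, 12 of 25 measured members rose at 4 h, 13 did not pass and none fell, and 14 rose when adjusted over the list alone. SGK1, a kinase that regulates sodium transport, rose from 254 ± 33 to 605 ± 39 (log2 1.23 ± 0.13), and DUSP1, a phosphatase of MAP kinases, from 1090 ± 180 to 2490 ± 210 (1.20 ± 0.13). SNAI2 rose by 1.44 ± 0.20, and FOXO3, BCL6, IRS2, GADD45A, SLC19A2, CRISPLD2, CEBPB and NFKBIA also rose. The list as a whole was higher (adjusted p = 9.68e-12, and adjusted p = 0.00303 with an estimated correlation). Of the inflammatory and NF-kB targets, 4 of 18 fell (CCL2, IER3, RELB and LIF), 14 did not pass, and 4 fell when adjusted over the list alone. This list was lower (adjusted p = 0.0112, but adjusted p = 0.0995 with an estimated correlation). Of 37 extracellular matrix genes, 4 rose: the collagens COL5A2 (log2 1.51 ± 0.29) and COL4A1 (0.96 ± 0.21) and the laminins LAMC1 and LAMB1. Adjusted over the list alone, 5 rose and 1 fell. The matrix list was higher (adjusted p = 0.0152), but adjusted p = 0.524 with an estimated correlation, and 0.053 without vehicle 4 h replicate 1. Interferon response genes had 0 of 25 members past the threshold, also when adjusted over the list alone. Their mean was -0.11, and 0.195 without rescaling, where the median of all probe sets was 0.369. The list was lower than other genes by camera (adjusted p = 0.0391, and adjusted p = 0.036 without rescaling). It did not pass with median centring (adjusted p = 0.075), cyclic loess (adjusted p = 0.057) or an estimated correlation (adjusted p = 0.416).

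The other 17 lists did not pass as lists at 4 h (adjusted p from 0.0587 to 0.926). Members that passed were the immediate early genes KLF4 and JUNB, which rose, and IER2 and FOSL1, which fell, of 15. Of 18 adhesion receptors and junction genes ITGA5, TJP1 and ITGB1 rose, and of 22 TGF-beta response genes TGFBR2 and CCN2. Of 16 MAPK phosphatase and ERK feedback genes PHLDA1 and DUSP14 fell. The epithelial sodium channel subunit SCNN1A rose from 26.4 ± 6.8 to 87.6 ± 19 (log2 1.42 ± 0.27), while the transporters SLC2A3 and SLC7A5 fell, of 17 transport genes. HSPA4 and DNAJA1 of 9 heat shock genes, BUB1B and MCM4 of 36 cell cycle genes, and PDGFC and WNT5A of 28 Wnt and growth factor genes rose. TXNRD1 of 27 antioxidant genes, PSAT1 of 18 unfolded protein and amino acid stress genes, and NCOA2 of 9 receptor and cofactor genes rose. ENO2 of 20 hypoxia and glycolysis genes fell. Of these risers KLF4, TJP1, ITGB1, TGFBR2, CCN2, HSPA4, DNAJA1, BUB1B, PDGFC and NCOA2 also rose in vehicle cells from 4 h to 16 h. That comparison uses the same vehicle 4 h arrays, so low values there would raise both changes. JUNB, ITGA5, SCNN1A, MCM4, WNT5A and TXNRD1 did not pass as rises with time, and PSAT1 fell. Adjusted over the list alone, 4 antioxidant genes rose and 6 fell, and 4 TGF-beta response genes rose and 3 fell. No member passed among 9 metallothioneins, 7 lens genes, 16 sterol synthesis genes, 17 apoptosis regulators and 7 circadian clock genes.

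In all, 767 of 12546 probe sets passed the threshold at 4 h, 656 higher and 111 lower with dexamethasone (492 and 99 named genes). The groups lay apart in all 767, and in 38.2% of all probe sets tested, where chance gives 10%. The share that was higher was 85.5%; it was 64.4% (371 of 576) with median centring, which moved the median of all probe sets from 0.063 to -0.088, and 99.5% (1086 of 1091) without rescaling, where that median was 0.369. The rescaled array median, the trimmed mean and the GAPDH ratio differed between the same groups. The 656 risers had a median change of 0.928 at 4 h and -0.0237 at 16 h, and stood 0.792 higher in vehicle at 16 h than in vehicle at 4 h. Of them 14 also rose with dexamethasone at 16 h, and 366 (55.8%) also rose with time in vehicle cells, where independent calls would share 62.2. The comparisons with dexamethasone and with time use the same 3 vehicle 4 h arrays, and no division of 3 arrays leaves at least 2 for each comparison, so part of this excess may come from the shared controls. Over all probe sets the changes in these comparisons had Pearson's r = 0.601 (simulated 0.449) and a covariance of 0.126 (simulated 0.030). The simulated noise was independent between probe sets and arrays. It holds no shift common to the vehicle 4 h arrays, so the excess cannot tell such a shift from a response. With 12 separate arrays the count was 1270. Without 1 array it was 379, 1567 or 114 (vehicle 4 h replicates 1, 2 and 3), 190, 39 or 48 (dexamethasone 4 h replicates 1, 2 and 3), 437 (vehicle 16 h replicate 2) and 1799 (dexamethasone 16 h replicate 2). Of 62 named calls, 8 passed under every alternative in which they were tested: CCL2, DUSP1, KLF4 (the brighter of its probe sets), SGK1, SNAI2, SOX4, SPDL1 and TSC22D3. Every alternative still compares with vehicle 4 h arrays. In vehicle cells from 4 h to 16 h SPDL1 (2.48 ± 0.35) and KLF4 (1.02 ± 0.17) also rose. With time TSC22D3 fell (-0.53 ± 0.14), and SOX4 and DUSP1 did not pass.

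**Figure D1:**
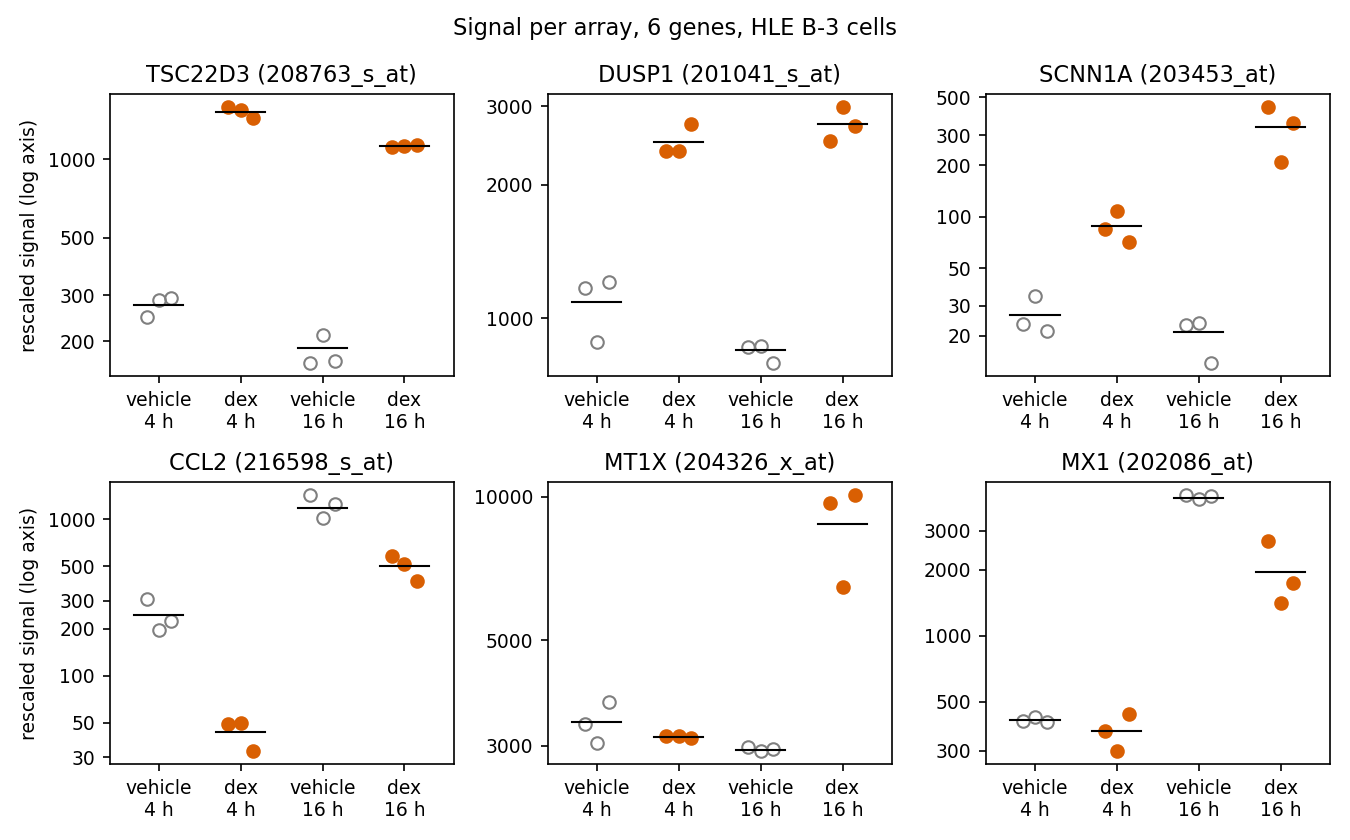
Rescaled signal (arbitrary units, log axis) of 6 genes on each of the 12 arrays, by group; open circles are vehicle, filled circles dexamethasone, and bars are group means with vehicle 16 h replicates 1 and 3 counted as 1 sample. TSC22D3, DUSP1 and SCNN1A were higher and CCL2 lower with dexamethasone at both times, while MT1X was higher and MX1 lower with dexamethasone at 16 h.

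The second comparison asked about the response after 16 h. SCNN1A (gene identifier 6337, chromosome 12, 6346847 to 6377359) rose from 21.1 ± 3.7 with vehicle (SD, n = 2) to 334 ± 120 with dexamethasone (n = 3), 10.6-fold after the pseudocount, with a log2 change of 3.41 ± 0.30 and an adjusted p of 8.8e-05. Its vehicle signal lies below the filter level of 40.65, so this fold depends on the pseudocount. TSC22D3 rose from 188 ± 32 to 1130 ± 14 (log2 2.53 ± 0.14), FAM107A by 1.94 ± 0.18, DUSP1 by 1.68 ± 0.15 and CRISPLD2 by 1.63 ± 0.15. NNMT, a methyltransferase that acts on nicotinamide, rose from 2040 ± 22 to 5570 ± 1300 (1.42 ± 0.17), and the metallothionein MT1X from 2940 ± 32 to 8750 ± 2000 (1.54 ± 0.17) by a probe set that is not its brightest. The neutrophil chemokine CXCL8 rose from 37.7 ± 5.2, also below the filter level, to 178 ± 68 (1.93 ± 0.35). TMT1A, PRUNE2, CHST7, CEBPB, FSTL3, DDIT4 and TPCN1 rose by 1.00 to 1.29. The secreted protein ANGPTL7 fell from 90.7 ± 25 to 20.1 ± 10 (-1.77 ± 0.30), and the receptor kinase GRK5 (-1.69) and CCL2 (-1.22) fell as well. TGFBRAP1, ENC1, MX1, PRSS23, MEST, C1orf115 and CKAP4 fell too, with log2 changes from -0.76 to -1.51. With dexamethasone the signals of ANGPTL7, GRK5, TGFBRAP1 and ENC1 (14.9 to 25.1) lay below the filter level, so these folds also depend on the pseudocount.

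Of the 25 glucocorticoid-induced genes, TSC22D3, DUSP1, CRISPLD2, CEBPB and SGK1 rose at 16 h, 20 did not pass, and 9 rose when adjusted over the list alone (list adjusted p = 2.32e-11, and adjusted p = 0.00366 with an estimated correlation). Of 25 interferon response genes, only MX1, an antiviral GTPase, fell over all genes tested, from 4260 ± 110 to 1950 ± 670 (-1.18 ± 0.22), and 8 fell when adjusted over the list alone, among them IFI35 (-0.79), OASL (-0.89) and BST2 (-0.87). The interferon list had a mean of -0.508 with 23 of 25 members below 0 (adjusted p = 2.12e-13, and adjusted p = 0.0139 with an estimated correlation). Metallothioneins, small metal-binding proteins, had 0 of 9 members past the threshold over all genes tested by their brightest probe sets, and 8 that rose when adjusted over the list alone, such as MT1F (0.92 ± 0.18), MT1H (1.10 ± 0.23) and MT2A (0.58 ± 0.17). That list was higher (adjusted p = 4.59e-08), but adjusted p = 0.112 with an estimated correlation. The genes of this family are so alike in sequence that probes of one may bind the RNA of another.

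The other 18 lists did not pass as lists at 16 h (adjusted p from 0.0631 to 0.922). CXCL8 rose and CCL2 fell among 18 inflammatory and NF-kB targets, whose mean (0.049) and test pointed in opposite directions. NFIL3, a transcription factor of the clock, rose among 7 circadian genes (0.96 ± 0.17), and SCNN1A among 17 transport genes. No member passed among 37 extracellular matrix genes, 7 lens genes, 36 cell cycle genes, 22 TGF-beta response genes, 18 adhesion genes or the rest. The receptor NR3C1 did not pass at 4 h or 16 h in any of its 4 probe sets. FKBP5 lay below the level filter, with 5.6 ± 2.4 in vehicle and 66.9 ± 10 in dexamethasone at 16 h; with no filter it rose by 2.29 ± 0.23 at 16 h (adjusted p = 0.00075) and had 0.49 ± 0.21 at 4 h (adjusted p = 0.23). Its vehicle signal is below the pseudocount, which limits these values. No probe set names PER1 alone.

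In all, 35 probe sets passed at 16 h, 25 higher and 10 lower (20 and 10 named genes). The groups lay apart in all 35, and in 25.2% of all probe sets tested, where chance gives 20% for 3 against 2. The share that was higher was 71.4%, and without rescaling it was 100% of 12. With 12 separate arrays the count was 156 (81 higher, 51.9%). Without 1 array it was 15 (vehicle 16 h replicate 2), 60 (dexamethasone 16 h replicate 2), 18 (dexamethasone 16 h replicate 3), 22 and 23 (dexamethasone 4 h replicates 1 and 3). Of 26 named calls, 7 passed under every alternative: CRISPLD2, DUSP1, FAM107A, MT1X, NNMT, SCNN1A and TSC22D3.

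**Figure D2:**
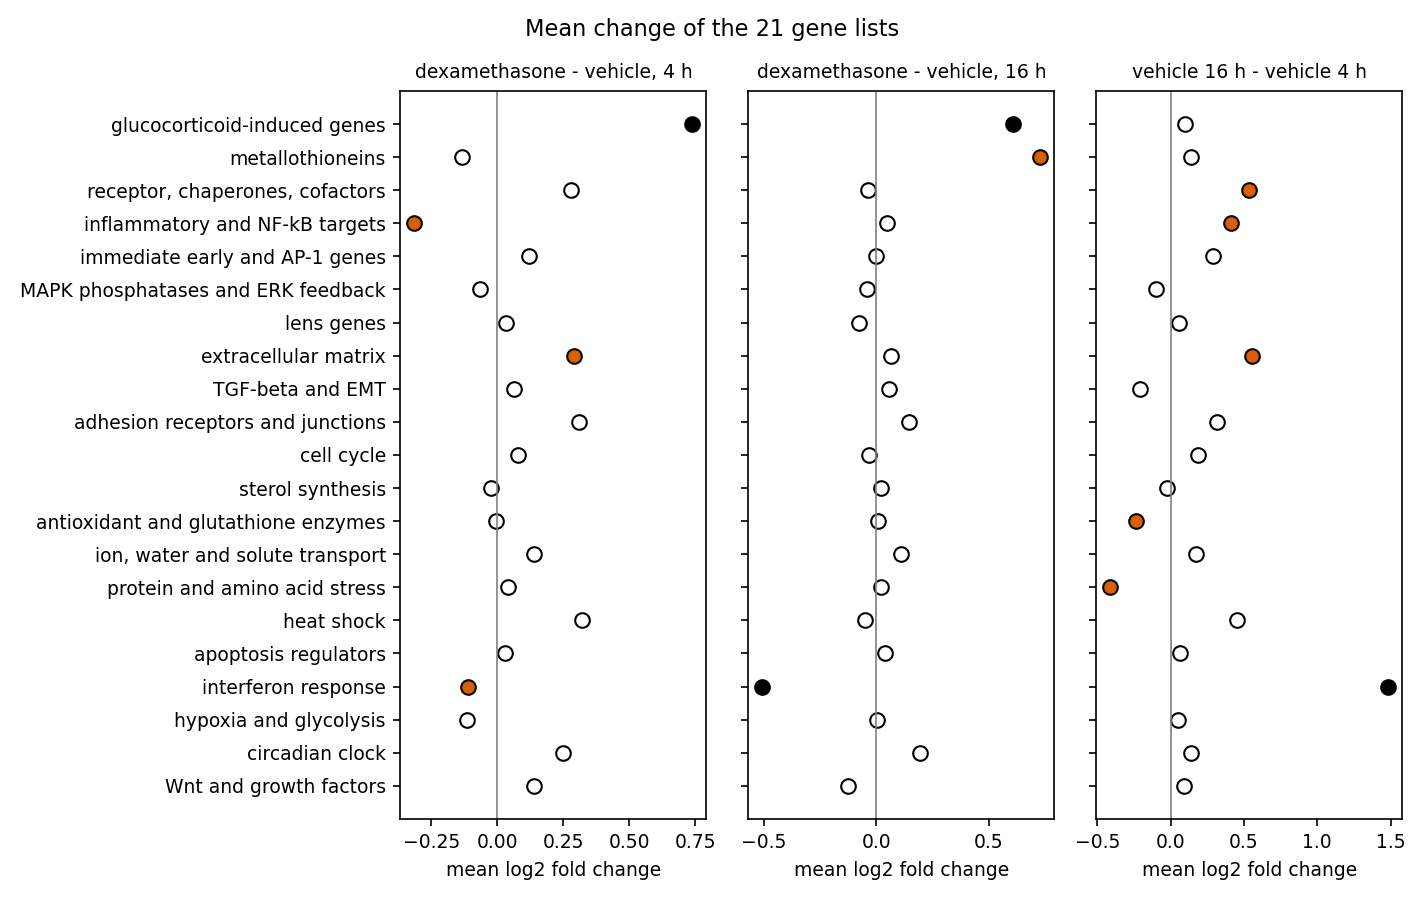
Mean log2 fold change (horizontal axis) of the 21 gene lists for dexamethasone against vehicle at 4 h and at 16 h and for vehicle at 16 h against 4 h. Black points passed the threshold also with an estimated correlation, orange points only with the preset correlation, and open points with neither: glucocorticoid-induced genes are black with dexamethasone at both times, and interferon response genes are black at 16 h (-0.508) and with time (1.485).

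The next comparison asked whether the effect of dexamethasone differed between 16 h and 4 h. Differences are given as the effect at 16 h minus that at 4 h. KLF4, by the brighter of its probe sets, went from 131 ± 22 to 410 ± 38 with dexamethasone at 4 h and from 274 ± 13 to 199 ± 26 at 16 h, a difference of -2.03 ± 0.23 (adjusted p = 0.0057). MT1X (1.63 ± 0.23) and NNMT (1.44 ± 0.23) rose at 16 h and did not pass at 4 h. POLD4, TRAP1 and MUS81 passed as falls at 4 h (-0.79, -0.55 and -0.58) and did not pass at 16 h, where their values were 0.54, 0.64 and 0.40. KRT7 had -0.38 at 4 h, which did not pass, and rose by 0.72 at 16 h. Of the genes with a negative difference (-1.40 to -1.98), SNAI2, DNAJA1, LAP3, LHFPL6 and the dynein heavy chain DYNC1H1 rose at 4 h and did not pass at 16 h. TGFBRAP1 had 0.40 at 4 h, which did not pass, and -1.51 at 16 h, which did. The potassium channel KCNMA1 had 0.79 at 4 h and -1.20 at 16 h, and passed at neither. Metallothioneins as a list had a positive difference (mean 0.862, adjusted p = 5.28e-05), but adjusted p = 0.359 with an estimated correlation; 0 of 9 passed over all genes tested and 7 when adjusted over the list alone. Interferon response genes had a negative one (mean -0.398, adjusted p = 0.0303), but adjusted p = 0.463 with an estimated correlation and 0.17 without dexamethasone 16 h replicate 2; 0 of 25 passed, also when adjusted over the list alone. The other 19 lists did not pass (adjusted p from 0.152 to 0.948).

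The interaction had 40 probe sets past the threshold, 7 higher and 33 lower (6 and 32 named genes), with 30.8% higher of 26 under median centring and 0% of 4 without rescaling in place of 17.5%. This count rests on single arrays. It was 0 in limma (1957 at an unadjusted p under 0.05) without vehicle 16 h replicate 2, where the lone vehicle 16 h sample is assumed to vary like the other groups, and 1 without vehicle 4 h replicate 1, any of the dexamethasone 4 h replicates 1, 2 and 3, or dexamethasone 16 h replicate 3. It was 14 without dexamethasone 16 h replicate 1, 22 without vehicle 4 h replicate 3, 26 without vehicle 16 h replicate 1, 455 without vehicle 4 h replicate 2 and 854 without dexamethasone 16 h replicate 2. With 12 separate arrays it was 707, and no named call passed under every alternative.

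By gene, counted by its brightest probe set, 398 rose at 4 h and 19 at 16 h, and 10 rose at both times, where 0.982 would be shared by independent calls (one-sided Fisher's exact p = 7.39e-09). These were TSC22D3, SCNN1A, SGK1, DUSP1, TMT1A, RHEX, FAM107A, CRISPLD2, DDIT4 and CEBPB; RHEX was outside the rule for named genes. For these 10 genes the test of the difference gave adjusted p from 0.053 (SCNN1A, log2 difference 2.00) to 0.83. Fisher's test takes genes as independent, and the 2 comparisons share each gene's variance estimate, so its p may be too small. Of 85 and 8 genes that fell, 1 was shared, CCL2 (0.0883 by chance, one-sided Fisher's exact p = 0.085). Of the 398 genes that rose at 4 h, 0 fell at 16 h, where independent calls would share 0.413, and the reverse was not counted. ENC1 fell at both times by different probe sets and is not counted as shared. Across all 7701 genes, which are not independent replicates, the effects at the 2 times had Pearson's r = 0.021 and Spearman's rho = -0.019. For the 27 genes past the threshold at 16 h r was 0.626, and for the 483 past it at 4 h it was 0.135. The 11 shared genes became 6 without rescaling, 17 with 12 separate arrays, 3, 4 and 6 without dexamethasone 4 h replicates 2, 3 and 1, 5 without vehicle 16 h replicate 2 and 6 without dexamethasone 16 h replicate 3.

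The last comparison described the background change of vehicle cells from 4 h to 16 h. Interferon response genes rose: 22 of 25 passed, 23 when adjusted over the list alone. MX1 went from 414 ± 11 (n = 3) to 4260 ± 110 (n = 2), 10.1-fold, with a log2 change of 3.33 ± 0.22 and an adjusted p of 1.6e-06. ISG15 went from 1600 ± 300 to 7610 ± 210 (2.26 ± 0.21), and IFITM1, OAS3 and IRF7 rose by 2.63, 1.83 and 2.12. The list had a mean of 1.485 (adjusted p = 2.25e-21, and adjusted p = 0.00681 with an estimated correlation), and of 0.696 without rescaling. RSAD2, INTS8, OAS2 and RTP4 were also among the largest rises. Asparagine synthetase, ASNS, fell from 2260 ± 240 to 142 ± 7.8 (14.9-fold, -3.90 ± 0.15), and so did PHGDH (-2.26 ± 0.18), the first enzyme of serine synthesis, ATF4 (-1.37), PSAT1 (-1.22), TRIB3 and CEBPG, while CANX and HSP90B1 rose. These belong to 18 unfolded protein and amino acid stress genes, of which 3 rose and 6 fell adjusted over the list alone (list adjusted p = 0.0488, but adjusted p = 0.138 with an estimated correlation and 0.095 with cyclic loess). The mean of this list was -0.411, and -1.198 without rescaling. CHAC1 (-2.31 ± 0.32), MYOD1 (-2.21 ± 0.28), FGFR3 (-1.95 ± 0.35) and KLHL35 (-1.95 ± 0.47) fell as well. The 16 h signals of MYOD1, FGFR3 and KLHL35 (13.2 to 29.3) lay below the filter level. So did the 4 h signals of RSAD2, INTS8, OAS2 and RTP4 (10.9 to 14.3), and all these folds depend on the pseudocount.

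Of 37 extracellular matrix genes 15 rose with time, led by COL6A1 (1.16 ± 0.15), FBN1, COL1A1 and COL1A2, and 21 rose adjusted over the list alone. This list was higher (adjusted p = 7.85e-07), but adjusted p = 0.138 with an estimated correlation, and its mean of 0.552 turned to -0.242 without rescaling. Among 27 antioxidant genes NQO1 (-1.23 ± 0.13), GPX1, GPX4, GLRX and PRDX4 fell, 5 also when adjusted over the list alone (adjusted p = 0.0284, but adjusted p = 0.118 with an estimated correlation), with a mean of -0.234 that was -1.026 without rescaling. CCL2, IL6, IRF1, TNFAIP2 and NFKB1 rose among 18 inflammatory and NF-kB targets, 6 when adjusted over the list alone (adjusted p = 0.0189, but adjusted p = 0.118 with an estimated correlation), with a mean of 0.415 that turned to -0.327 without rescaling. NCOA2, NCOA1 and NR3C1 rose among 9 receptor, chaperone and cofactor genes, 5 rising and 1 falling when adjusted over the list alone (adjusted p = 0.0488, but adjusted p = 0.161 with an estimated correlation), with a mean of 0.531 that turned to -0.291 without rescaling. The median of all probe sets was -0.742 without rescaling, so a turned mean does not show that a list turned relative to other genes.

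Time moved 1886 probe sets, 1189 higher and 697 lower at 16 h, and 53% of all probe sets had groups apart, where chance gives 20%. The share that was higher was 63%, against 48.8% of 1924 with median centring and 1.29% of 5112 without rescaling, which moved the median of all probe sets to -0.742. At the same time the trimmed mean was lower at 16 h (149.2, 120.6 and 142 on the 3 arrays, counted as 2 samples) than at 4 h (236 ± 13, n = 3, exact permutation p = 0.1). The GAPDH ratio was higher at 16 h (0.931 ± 0.0025 against 0.893 ± 0.010, exact permutation p = 0.1). The same ratio for ACTB went the other way (0.968 ± 0.019 against 1.17 ± 0.096, exact permutation p = 0.2). The count was 1226 and 966 without vehicle 4 h replicates 1 and 3, 499 without vehicle 16 h replicate 2, and 3256 with 12 separate arrays.

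**Figure D3:**
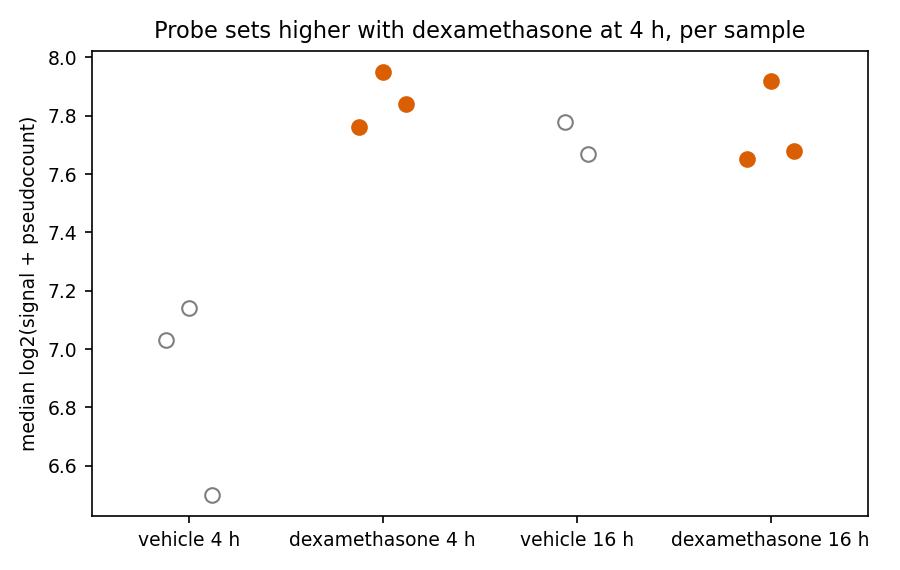
Median log2 signal, in each of the 11 samples, of the 656 probe sets that were higher with dexamethasone at 4 h. The vehicle 4 h samples lie at 6.50 to 7.14 and the dexamethasone 4 h samples at 7.76 to 7.95. The probe sets were chosen by the difference between these groups, so a gap between them follows from the choice. All 16 h samples, vehicle and dexamethasone, lie between 7.65 and 7.92.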

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

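The tests with cyclic loess, with vehicle arrays left out in turn, of the interferon list without 1 array and over 4 scalings, over splits with the 4 h groups kept, and of the near-identical arrays were chosen only after the result was seen. The spread within the 16 h groups, the other splits of the samples and the correlation over the interferon list were set down before.

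The largest positive differences in limma's interaction test (effect at 16 h minus that at 4 h, signed) were those of MT1X (1.63), NNMT (1.44), POLD4 (1.33), TRAP1 (1.19), KRT7 (1.10) and MUS81 (0.98). POLD4, TRAP1 and MUS81 fell at 4 h and did not pass at 16 h. The largest negative ones were those of KLF4 (-2.03), KCNMA1 (-1.98), TGFBRAP1 (-1.91), LAP3 (-1.78), LHFPL6 (-1.70) and DYNC1H1 (-1.68), of which TGFBRAP1 passed only as a fall at 16 h. Of the gene lists, metallothioneins differed by a mean of 0.86 and the interferon response by -0.40, neither past the threshold with an estimated correlation (adjusted p = 0.359 and 0.463). Of 100 splits of the samples within each time, 3 gave at least the real count of 40 interaction calls, the real split included, and all 3 kept the real 4 h groups. With those groups kept there are only 10 splits of the 16 h samples, 3 of them with at least 40 calls, too few for a share under 0.05. The highest other split gave 675. These splits keep the difference between the 4 h groups, which by itself enters the interaction, so they do not show what chance gives. Without dexamethasone 16 h replicate 2 the count was 854.

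At 4 h, 85.5% of the 767 calls were higher with dexamethasone. After cyclic loess, which removes differences in scale that depend on the level, 80.7% of the calls were still higher. This argues against such a difference as the whole cause, under 1 scaling chosen after the result was seen. The share was 81.5% with quantile normalization, 64.4% with median centring and 99.5% without rescaling, so scale as part of the cause stays open. A difference between samples in RNA or labelling stays open: within the 16 h groups the median of these probe sets differed by up to 0.27 between samples, between the bounds set for and against it. Low values in the vehicle 4 h samples stay open too: probe sets chosen against the other vehicle 4 h arrays stood 0.87 times as far above the array left out in vehicle at 16 h as in dexamethasone at 4 h, which time in culture may also give, and the design confounds both. An effect of dexamethasone stays open as well; 1 of the 10 splits of the 6 samples, the real one, gave 767 calls and the highest other gave 0, but 10 splits are too few for a share under 0.05.

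Interferon response genes were lower with dexamethasone at 16 h (mean -0.508). Without dexamethasone 16 h replicate 2 the adjusted p of the list, by camera at its preset correlation, was 3.3e-10. This argues against that array alone as the cause. Camera with an estimated correlation, which gave an adjusted p of 0.0139 with all arrays, was not run without that array. A difference in array scale is argued against by the mean of the list, which was at most -0.445 under quantile normalization, cyclic loess, median centring and no rescaling. A candidate explanation is that dexamethasone held back the rise of these genes over time in culture: over 25 genes, the rise with time and the effect of dexamethasone, computed with no array in common, had Pearson's r = -0.582 (permutation p = 0.002) and Spearman's rho = -0.568 (permutation p = 0.0037), and r was -0.47 without MX1 and IFI6. This is a hypothesis found and tested on the same samples, its genes are not independent replicates, and a difference between the 16 h cultures other than the treatment was not tested.

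Vehicle 16 h replicates 1 and 3 differed by a median absolute deviation of 0.0366 in the log2 ratio of their brightest probe sets, where the other replicate pairs had at least 0.15. The value is consistent with 1 RNA sample measured on 2 arrays, and the spread at lower signals (0.24 against at least 0.328 for signals from 40.6 to 163) goes the same way. The labels do not say so, and no biological explanation was tested.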

How the results depend on the processing

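Cyclic loess, 12 separate arrays, array quality weights and leaving out dexamethasone 16 h replicate 2 and vehicle 4 h replicate 3 together were chosen after the data were seen; the other alternatives were planned. The cause of a change was not tested. No named call turned direction except without rescaling. Named calls that passed under every alternative in which they were tested were 8 of 62 at 4 h, 7 of 26 at 16 h, 0 of 14 for the interaction and 28 of 75 with time.

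The 767 calls with dexamethasone at 4 h became 422 with quantile normalization, 226 with no level filter, 372 with no variance trend, 1270 with 12 separate arrays and 4677 with array weights. The array weight fit stopped before it converged, with weights from 0.24 to 7.58. Without 1 array the count was 379, 1567 and 114 (vehicle 4 h replicates 1, 2 and 3), 190, 39 and 48 (dexamethasone 4 h replicates 1, 2 and 3), 437 (vehicle 16 h replicate 2) and 1799 (dexamethasone 16 h replicate 2), from 39 to 1799 in all. The 35 calls at 16 h became 12 with no rescaling, 18 with only the arrays of the comparison, 156 with 12 separate arrays, 107 with array weights and 97 without both dexamethasone 16 h replicate 2 and vehicle 4 h replicate 3. Without 1 array they ran from 15 (vehicle 16 h replicate 2) to 60 (dexamethasone 16 h replicate 2), with 22 and 23 without dexamethasone 4 h replicates 1 and 3 and 18 without dexamethasone 16 h replicate 3.

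The 40 interaction calls became 4 with no rescaling, 26 with median centring, 76 with a pseudocount of 20%, 2 with no level filter, 86 with a level filter of 40%, 1 with no variance trend, 707 with 12 separate arrays, 2030 with array weights and 729 without both dexamethasone 16 h replicate 2 and vehicle 4 h replicate 3. Without 1 array they ran from 0 (vehicle 16 h replicate 2) to 854 (dexamethasone 16 h replicate 2); the others past 1.5 times were 1 (vehicle 4 h replicate 1, dexamethasone 4 h replicates 1, 2 and 3, and dexamethasone 16 h replicate 3), 14 (dexamethasone 16 h replicate 1), 22 (vehicle 4 h replicate 3), 26 (vehicle 16 h replicate 1) and 455 (vehicle 4 h replicate 2). The 1886 calls with time became 5112 with no rescaling, 3256 with 12 separate arrays and 4519 with array weights, and ran from 499 (vehicle 16 h replicate 2) to 2644 (dexamethasone 16 h replicate 2) without 1 array, with 1226 and 966 without vehicle 4 h replicates 1 and 3. Without vehicle 16 h replicate 2, the lone sample of that group is assumed to vary like the other groups.

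The replicate number as a block, fitted on 12 separate arrays, gave 924, 112, 270 and 3032 calls at 4 h, at 16 h, for the interaction and for time. No pairing of the samples by number was seen. Deviations of same-numbered arrays from their groups had correlations of -0.193, 0.114 and 0.060 at 4 h and 0.070, -0.003 and -0.053 at 16 h. So few values cannot exclude that a number marks a shared culture or day.

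The 11 genes called at both times became 6 with no rescaling, 7 with no level filter, 7 with no variance trend, 17 with 12 separate arrays and 24 with array weights, and 3 (without dexamethasone 4 h replicate 2) to 15 (without vehicle 16 h replicate 3) without 1 array. The 7 lists past the threshold in the dexamethasone comparisons became 3 with an estimated correlation, and 5 to 9 without 1 array.

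No rescaling lowered the median change with time to -0.742 and turned named genes over: ATP2A2 -0.08, BAX -0.14, BHLHE40 -0.40, BUB1B -0.02, COL1A1 -0.04, DUSP5 -0.21, EGFR -0.11, IRF1 -0.05, ITGB5 -0.07, MT2A -0.50, NCOA1 -0.12, NFIL3 -0.19, P4HA1 -0.05, PAX6 -0.68, SFRP1 -0.02 and TNFAIP2 -0.13. Signals near the filter vary most between arrays, and 12546 of 22215 probe sets passed it.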

Other observations

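In vehicle cells from 4 h to 16 h, single members of several gene lists passed, while the lists themselves did not. Among 22 TGF-beta response genes the smooth muscle proteins TAGLN (log2 -1.51 ± 0.13, from 5740 ± 380 to 2000 ± 15) and ACTA2 (-0.81 ± 0.15) and the inhibitors of differentiation ID1, ID2 and ID3 fell, while TGFBR2, CCN2 and TGFB2 rose (list adjusted p = 0.0901). Of 17 transport genes, the amino acid transporters SLC7A5 (-1.74 ± 0.13) and SLC1A5 (-1.13 ± 0.14) fell, and the water channel AQP1 rose from 359 ± 47 to 1020 ± 82 (1.48 ± 0.15), as did ATP2A2, ATP1B3, ATP2B4 and SLC5A3. DNAJA1, HSPA4, HSPD1 and HSPH1 rose among 9 heat shock genes. IGFBP3 (-1.19 ± 0.15), IGFBP4 and DKK3 fell among 28 Wnt and growth factor genes, of which EGFR, PDGFC, SFRP1, GAS6, TCF7L2 and FZD7 rose.

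Also with time, MCM6, CDK1, CCNE2, BUB1B and TOP2A rose among 36 cell cycle genes, and TJP1, ITGAV, CDH11, ITGB5, VCL and ITGB1 among 18 adhesion genes. Of 17 apoptosis regulators MCL1 and BAX rose, and BAK1, BIRC5 and BCL2L1 fell. KLF4 and EGR1 rose and JUND fell among 15 immediate early genes, SPRY2 and DUSP5 rose and DUSP2 and PHLDA1 fell among 16 MAPK phosphatase and ERK feedback genes, and the gap junction protein GJA1 rose among 7 lens genes. Without rescaling, where the median of all probe sets was -0.742, the values of ATP2A2, BAX, BUB1B, DUSP5, EGFR, ITGB5 and SFRP1 turned negative.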
